A study of Mus musculus with 48 samples.

How the data were processed

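Gene expression was measured in whole-kidney RNA of 48 mice, with 1 Affymetrix mouse array per animal. Per the labels' protocols, RNA was taken from frozen whole kidneys and the submitters looked over array density, RNA degradation and MA plots by eye. The labels give strain (FVB or C57BL/6, written B6 here), surgery (subtotal nephrectomy, written Nx, or sham operation) and day after surgery (2, 28 or 53), which makes 12 groups of 4 arrays. All animals were 9 weeks old at surgery per the labels, and each animal is named by its group and the mouse number of its label. A mouse number recurs under Nx and sham labels of the same strain and day, and the values do not settle whether such numbers pair animals. Deviations of same-numbered arrays from their group means correlated across genes between -0.251 and 0.378. In FVB at day 28, arrays with different numbers ranged from -0.577 to 0.469. The same-numbered pair was the highest in B6 at day 2 (0.281, next 0.177) and day 53 (0.225, next 0.151). In FVB at day 2, 1 of 4 same-numbered pairs was the highest (0.127, next 0.081), and the others lay at 0.071, 0.003 and -0.002. The arrays were treated as unpaired, with mouse number as a block among the alternatives.

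The deposited table holds log2 values for 45101 probe sets, as judged from the values themselves, which run from 2.1979 to 16.1753. The submitters' processing notes name MAS5 without saying what it was used for, and how the authors corrected background, summarised probes and normalised arrays is not stated. The deposited values share 1 lowest value on all 48 arrays, and 32.057% of all values lie at it (31.1% to 32.7% per array). Array medians lay between 3.168 and 3.441 on the log2 scale and no pair of arrays was identical, so the values were used as deposited, with no further scaling and no pseudocount. A change that starts from the lowest value is a lower bound. Where all 4 arrays of a group lay at or under the filter value, the fold is given as at least the ratio to that filter value. For arrays, their number limits the precision, here 4 per group.

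Probe sets were joined to genes by exact identifier with the annotation supplied for the platform. Of 45101 probe sets, 35890 were listed there, 34958 of them with 1 gene symbol and 932 with several, and 9211 were not listed. The 64 control probe sets were left out of the tests. A probe set was kept when its value passed the 40th percentile of all values (2.277) in at least 4 arrays, which left 29274 probe sets, 24197 of them with 1 symbol. Each gene was represented by its kept probe set with the highest mean over all arrays, which gave 13174 genes, 6290 of them with more than 1 kept probe set.

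Comparisons were made with limma 3.58.1 in R 4.3.3, with a mean for each of the 12 groups, all 48 arrays in 1 fit (36 residual degrees of freedom) and eBayes with an intensity trend (median prior degrees of freedom 2.62). P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 13174 genes of each contrast, with 0.05 as the threshold. There were 14 contrasts: Nx against sham in each strain at each day (6), the difference of the Nx effect between the strains at each day (3), the change of the Nx effect between successive days in each strain (4), and FVB against B6 over the sham animals of all days (1). Errors of fold changes are standard errors (SE) of that fit, and errors of group means are standard deviations (SD). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served to read the table and draw the plots.

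The groups, contrasts, test, filter, alternatives, rule for naming genes and 33 lists of genes by pathway, cell type and other tissues were fixed before the data were examined. For a surgery contrast, the rule names the 8 genes with the highest and the 8 with the lowest fold change among those past the threshold whose 4 Nx and 4 sham values do not overlap, and for the other contrasts the 5 highest and the 5 lowest past the threshold. Unnamed or provisional gene models are skipped, and up to 4 members of each list with the smallest p are named as well. Each list was tested with limma's camera at its preset correlation between genes and again with the correlation estimated, adjusted over the lists of a contrast. The 31 lists with at least 3 measured genes were tested this way. Each list is also given as the number of members past the threshold over all genes and the number when adjusted over the list alone. Camera asks whether a list differs from the other genes, and the list mean per animal whether Nx differs from sham, so a list can pass only 1 of these tests. List means per animal were compared by exact permutation tests, two-sided, for which 4 against 4 animals allow no p below 0.0286.

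After the data were examined, 3 lists were added to follow RNA of other tissues and 5 lists for the observations that close the document. Alternatives fixed in advance were quantile normalisation, a median shift per array, no filter, a filter at the 60th percentile (5.184), the mean of a gene's probe sets, the arrays of a comparison alone, eBayes without trend and with a robust trend, array weights, mouse number as a block, and leaving out each array in turn. Added after the data were examined were other-tissue list means as covariates, the 3 prime to 5 prime differences of control probe sets as covariates, and leaving out arrays with pancreatic transcripts. The fit was tested on simulated data drawn from normal distributions with the mean and spread of each gene, with known changes added to the FVB Nx day 53 group. Changed genes were drawn from those of intermediate mean, and each gene varied independently with the same spread in all groups. In the real data Nx groups varied more than sham groups, so the rates below need not hold for them or for dim genes. For Nx against sham in FVB at day 53 it recovered 64% of 50 genes changed by 0.5 on the log2 scale, 94% of those changed by 1 and 100% of those changed by 2. For the strain difference at day 53 it recovered 30%, 80% and 100%, and 0.069% of 12954 unchanged genes were called.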

Results

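Subtotal nephrectomy leaves mice with a small remnant of kidney, and the 2 strains studied here were chosen because FVB mice are predisposed to lesions in that remnant and B6 mice are not. The question throughout is which genes and cell programs the remnant changes at day 2, day 28 and day 53 after surgery, and where the strains part. Each of the 12 groups held 4 animals, and every adjusted p-value below comes from limma unless another test is named. Surgery set the arrays apart most: the first principal component, which separated Nx from sham kidneys, held 47.6% of the variance, and the component that separated the strains held 15.1%. Compared with sham, 7221 of 13174 genes differed in FVB kidneys at day 2, 2129 at day 28 and 7075 at day 53, against 5874, 2501 and 1938 in B6 kidneys. The next component (9.1%) followed transcripts of pancreatic enzymes, whose mean lay above 5 on the log2 scale on 16 of 24 Nx arrays and 2 of 24 sham arrays (Fisher exact test, two-sided, p = 5.78e-05). The Gapdh 3 prime minus 5 prime difference, a measure of RNA integrity, was higher in Nx than in sham kidneys at day 2, at 0.303 against 0.156 in FVB and 0.307 against 0.139 in B6. The Actb difference was lower in FVB Nx kidneys at day 53 (-0.268). Each had an exact permutation p of 0.0286, two-sided, and 0.172 when adjusted over the measures and groups.

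**Figure D1:**
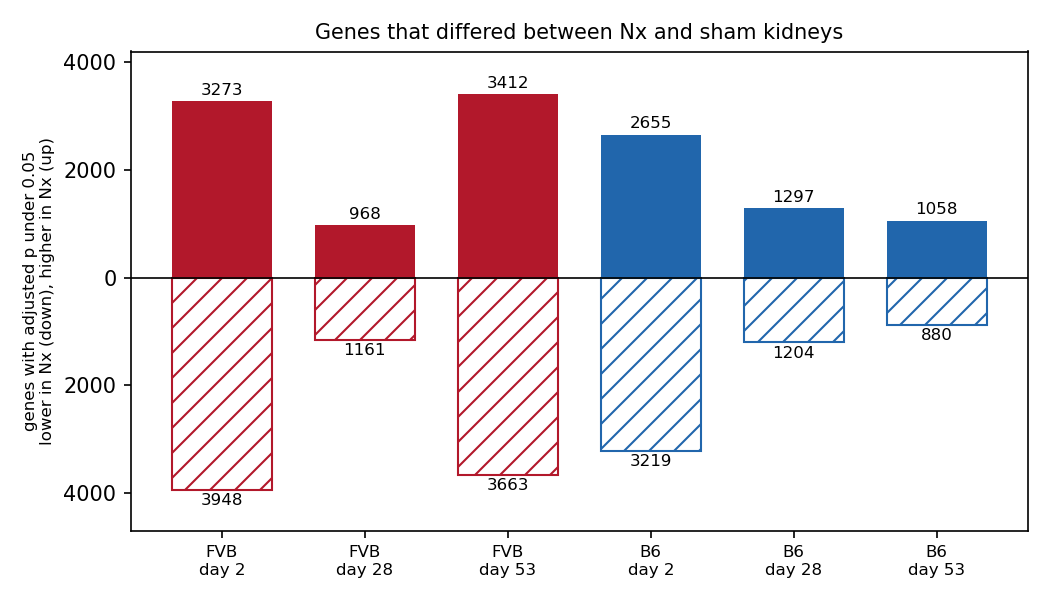
Number of genes with an adjusted p under 0.05 in Nx against sham kidneys (y axis), higher in Nx above the line and lower in Nx below it, for FVB (red) and B6 (blue) at days 2, 28 and 53. Each group held 4 animals, and the bars run from 880 to 3948 genes.

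What does the FVB remnant express at day 2, while it is still responding to the operation? Matrix metalloproteinase Mmp12 of macrophages rose 555-fold (log2 9.12, SE 0.58, adjusted p = 2.17e-15), the glycoprotein Gpnmb 330-fold (8.37, SE 0.55, adjusted p = 4.23e-15) and the injury marker Lcn2 229-fold (7.84, SE 0.44, adjusted p = 7.18e-17). The chemokine Ccl8 rose 144-fold (7.17, SE 0.68, adjusted p = 1.9e-11), the collagen chain Col1a1 99.2-fold (6.63, SE 0.42, adjusted p = 2e-15) and the interferon-induced Slfn4 at least 81.4-fold (6.41, SE 0.31, adjusted p = 1.13e-18). The macrophage lectin Clec4n and the protease inhibitor Timp1 completed the 8 largest rises among genes whose Nx and sham values do not overlap. The same limit holds for the largest rises and falls of every surgery comparison below. Among the 8 largest falls were the cytochrome Cyp2d12 (-5.30, SE 0.49, adjusted p = 1.2e-11), Fam151a (-4.36, SE 0.27, adjusted p = 1.54e-15), the tyrosine-degrading enzyme Hpd (-4.29, SE 0.52, adjusted p = 5.43e-09) and the phosphate transporter Slc34a3 (-3.88, SE 0.37, adjusted p = 2.41e-11). Syn3, Serpina6, Clec2h and Nepn were the others. In all, 3273 genes were higher and 3948 lower.

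In the same FVB kidneys, lists of cell cycle, matrix and immune genes were higher at day 2. All 23 genes of monocytes and macrophages were higher (median log2 3.70, camera adjusted p = 2.96e-16, adjusted p = 0.114 with an estimated correlation). So were 26 of 28 genes of extracellular matrix and fibrosis, with 2 not passed (3.45, camera adjusted p = 5.88e-20, adjusted p = 0.109 with an estimated correlation). Of 31 cell cycle genes, 28 were higher and 3 were not passed (2.72, camera adjusted p = 7.48e-16, adjusted p = 0.113 with an estimated correlation). Among them was the mitotic kinase Aurka (3.23, SE 0.21, adjusted p = 4.23e-15). The interferon response was higher in all 19 genes (2.00, camera adjusted p = 1.22e-10, adjusted p = 0.113 with an estimated correlation). Its regulator Irf7 rose at least 6.84-fold (adjusted p = 1.29e-17). Of 17 tubular injury genes, 15 were higher, 16 when adjusted over the list alone (2.10, camera adjusted p = 1.22e-10, adjusted p = 0.0721 with an estimated correlation). The keratin Krt20 rose by 3.64 (SE 0.21). Cytokines and chemokines were higher in 23 of 28 genes (24 when adjusted over the list alone; 2.40, camera adjusted p = 1.49e-10, adjusted p = 0.109 with an estimated correlation). All 6 neutrophil genes were higher (2.61, camera adjusted p = 0.00474, adjusted p = 0.194 with an estimated correlation).

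Transcripts of tubule function ran the other way in FVB kidneys at day 2. Of 29 genes of proximal tubule transport, 23 were lower, 1 higher and 5 not passed (median log2 -1.14, camera adjusted p = 1.5e-10, adjusted p = 0.141 with an estimated correlation). The amino acid transporter subunit Slc7a7 fell by 3.39 (SE 0.24, adjusted p = 2e-14). Oxidative phosphorylation was lower in 29 of 31 genes, by less (-0.41, camera adjusted p = 7.92e-11, adjusted p = 0.153 with an estimated correlation). The loop of Henle and distal tubule was lower in 17 of 18 (-0.81, camera adjusted p = 2.27e-06, adjusted p = 0.125 with an estimated correlation). The collecting duct was lower in 15 of 18 genes and higher in 1 (-1.03, camera adjusted p = 8.37e-05, adjusted p = 0.181 with an estimated correlation). Of 20 pancreatic enzyme genes, 19 were higher on the same arrays (median log2 7.75), and these transcripts move with the surgery groups. Shifting every array to 1 median moved the median change of all genes from -0.0325 to -0.117 and the split from 3273 higher and 3948 lower to 2741 and 5010.

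Does the B6 remnant, which resists lesions, start differently at day 2? Among genes without overlap of Nx and sham values, leading rises were shared: Gpnmb 214-fold (log2 7.74, SE 0.55), Mmp12 169-fold (7.40, SE 0.58) and Lcn2 90.5-fold (6.50, SE 0.44, adjusted p = 1.5e-14). The neutrophil chemokine Cxcl5 rose at least 49.0-fold (adjusted p = 7.59e-18), the tubule protease Mmp7 at least 44.3-fold (adjusted p = 1.5e-14), and the elastic fibre genes Fbn2 and Ltbp2 by 5.66 (SE 0.50) and 5.60 (SE 0.43). Rnase1, which the pancreas makes, was among the 8 highest (6.40, SE 2.60, adjusted p = 0.0427), beside 10 of 20 pancreatic enzyme genes that were higher (14 when adjusted over the list alone). Cyp2d12 (-4.65, SE 0.49), Hpd (-3.96, SE 0.52), Slc34a3 (-3.77, SE 0.37) and the methyltransferase Inmt (-3.75, SE 0.39) fell. The histamine-forming Hdc and Clec2h fell as well. Brown fat genes lay among these falls, Ucp1 at -5.18 (SE 1.49, adjusted p = 0.00416) and Cox8b at -3.96 (SE 1.16). Of 5874 genes, 2655 were higher and 3219 lower.

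Cell division was the clearest program in B6 kidneys at day 2: 30 of 31 cell cycle genes were higher and 1 was not passed (median log2 3.43, camera adjusted p = 1.72e-28, 0.0221 estimated), and Aurka rose at least 16.4-fold. Tubular injury was higher in 15 of 17 genes (1.93, camera adjusted p = 3.68e-13, 0.0221 estimated), led by Krt20 (4.98, SE 0.21, adjusted p = 1.15e-20). Matrix and fibrosis genes were higher in 27 of 28 (28 when adjusted over the list alone; 2.51, camera adjusted p = 3.29e-22, adjusted p = 0.06 with an estimated correlation). Macrophage genes were higher in 22 of 23 (2.51, camera adjusted p = 2.14e-15, adjusted p = 0.112 with an estimated correlation). Nrf2 targets, which answer oxidative stress, were higher in 11 of 16 and lower in 1 (0.86, camera adjusted p = 0.000104, adjusted p = 0.06 with an estimated correlation). Nqo1 rose by 2.72 (SE 0.21, adjusted p = 4.08e-13). Proximal tubule transport was lower in 24 of 29 genes and higher in 1 (-1.01, camera adjusted p = 2.87e-11, adjusted p = 0.112 with an estimated correlation). Oxidative phosphorylation was lower in 22 of 31 (-0.18, camera adjusted p = 9.29e-05, adjusted p = 0.422 with an estimated correlation). The loop of Henle and distal tubule was lower in 13 of 18 genes (-0.45, camera adjusted p = 0.000439, adjusted p = 0.267 with an estimated correlation). The interferon list did not pass against the other genes in B6 (6 higher, 1 lower, 12 not passed; 0.37, camera adjusted p = 0.109), yet its mean per animal lay above sham without overlap at day 2 (0.431), day 28 (0.523) and day 53 (0.527; exact permutation p = 0.0286 each, two-sided).

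Which parts of the day 2 response depend on strain? Across all genes the Nx effects of the strains correlated at 0.885 (Pearson; Spearman 0.849; genes are not independent replicates), 2136 genes were higher in both strains against 660 expected by chance, 2633 were lower in both against 965, and 23 went opposite ways. The interaction passed for 581 genes, 299 with a higher effect in FVB and 282 with a lower one. This count depends on single animals: it was 343 without FVB Nx day 2 mouse 2 and 951 without FVB Nx day 2 mouse 5. With only the arrays of the comparison it was 324. The interferon response set the strains apart: 13 of 19 genes had a higher effect in FVB and 6 were not passed (median log2 1.73, camera adjusted p = 1.39e-24, 0.0122 estimated). Among its members were Irf7 (difference of effects 2.51, SE 0.21, adjusted p = 7.59e-11), Stat2 (1.44, SE 0.14, adjusted p = 1.4e-09) and Usp18 (3.36, SE 0.52). Outside the list, the effect was higher in FVB for Slfn4 (5.90, SE 0.44, adjusted p = 4.67e-12), Ms4a4c (4.58, SE 0.60), Ifi202b (4.49, SE 0.55), Ccl8 (4.36, SE 0.96, adjusted p = 0.00429) and the acute phase gene Saa3 (5.49, SE 1.34, adjusted p = 0.0113). The effect was lower in FVB for Serpina1b (-5.25, SE 0.76), Serpina6 (-3.76, SE 0.52), Il5ra (-3.25, SE 0.31), Mmp7 (-2.99, SE 0.53), the kinetochore gene Nuf2 (-3.15, SE 0.36) and Krt20 (-1.34, SE 0.30). Serpina1b and Serpina6 differed between the strains already in sham kidneys.

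Other lists differed less at day 2. Of 31 cell cycle genes, 1 had a higher effect in FVB and 5 a lower one, 1 and 9 when adjusted over the list alone (median log2 -0.38, camera adjusted p = 4.16e-05, adjusted p = 0.649 with an estimated correlation). Oxidative phosphorylation genes had a lower effect in FVB in 5 of 31, 21 when adjusted over the list alone (-0.22, camera adjusted p = 4.14e-12, adjusted p = 0.487 with an estimated correlation). Macrophage genes had a higher effect in 3 of 23, 8 over the list alone (1.11, camera adjusted p = 4.87e-07, adjusted p = 0.649 with an estimated correlation). Tubular injury did not pass (0 higher, 1 lower, 16 not passed; camera adjusted p = 0.33).

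**Figure D2:**
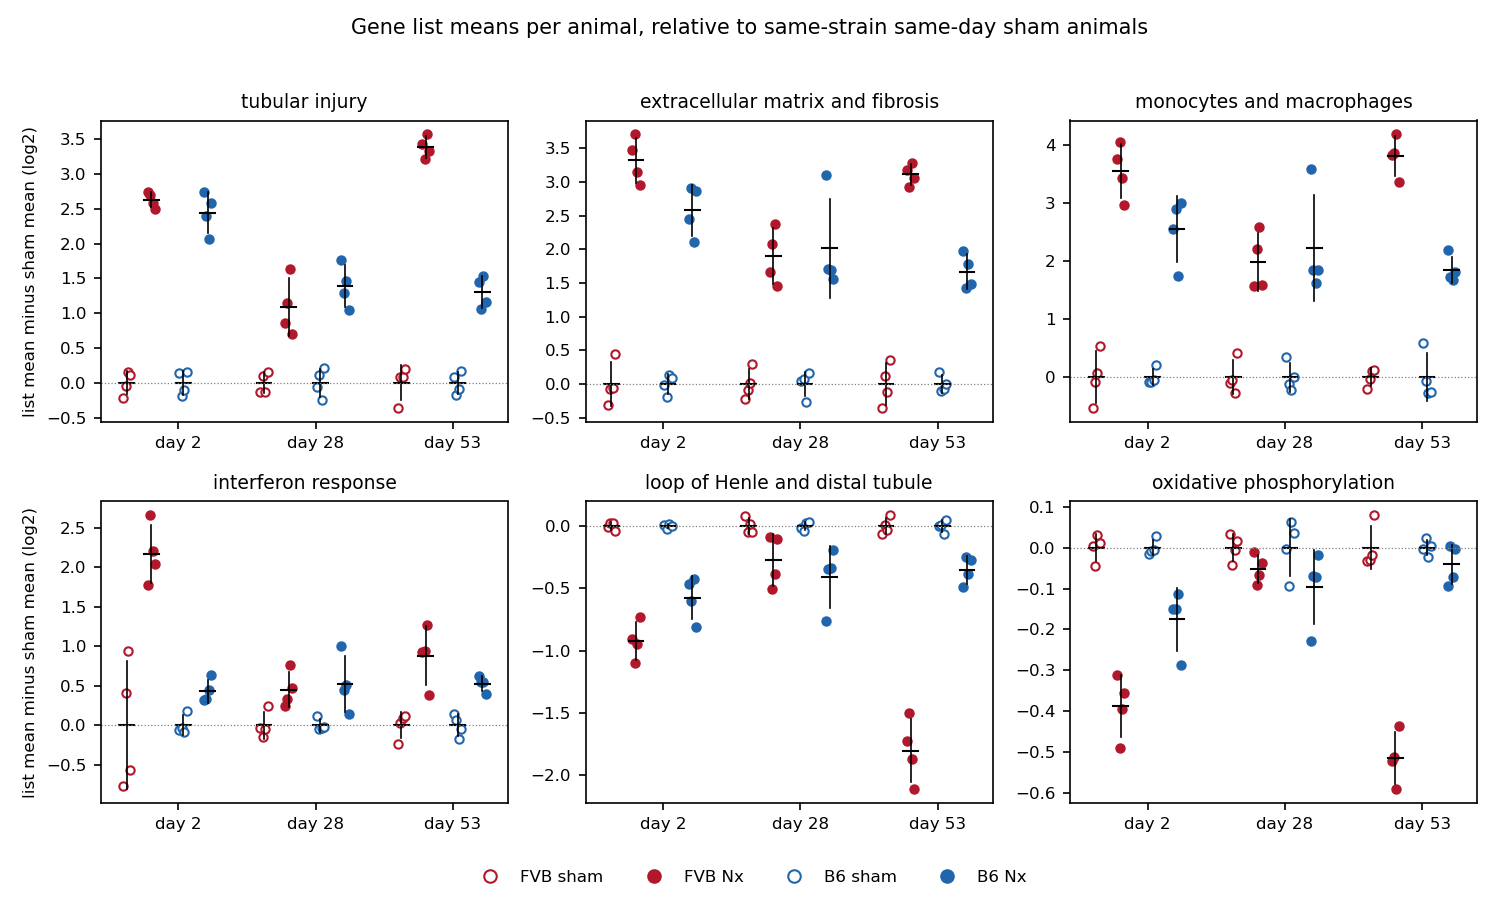
Mean of each gene list per animal minus the mean of the sham animals (log2, y axis) for sham (open) and Nx (filled) kidneys of FVB (red) and B6 (blue) at days 2, 28 and 53, 4 animals per group. Lines are means and bars SD.

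By day 28 the question is what persists once the acute phase has passed. In FVB kidneys Mmp12 stayed 125-fold above sham (log2 6.97, SE 0.58, adjusted p = 9.65e-11), Gpnmb 62.2-fold (5.96, SE 0.55), Ccl8 27.2-fold (4.76, SE 0.68, adjusted p = 3.09e-06), Col1a1 23.6-fold (4.56, SE 0.42, adjusted p = 5.79e-10) and Lcn2 by 3.96 (SE 0.44, adjusted p = 3.57e-08). The lysosomal macrophage marker Cd68 rose by 4.10 (SE 0.49, adjusted p = 1.54e-07), with Saa3 (4.54, SE 0.95), Serpinf1 (4.25, SE 0.65) and F13a1 (4.17, SE 0.78). The steroid-binding globulin Serpina6 (-4.48, SE 0.37, adjusted p = 8.49e-11), Hdc (-3.89, SE 0.64, adjusted p = 2.66e-05), the water channel Aqp4 (-2.87, SE 0.65, adjusted p = 0.00147) and Slc6a15 (-2.59, SE 0.29) fell. Of 2129 genes, 968 were higher and 1161 lower, and the count was 635 without the arrays with pancreas transcripts, which leaves 1 Nx array.

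Matrix and macrophage lists were higher in FVB kidneys at day 28. Matrix and fibrosis genes were higher in 23 of 28 (25 when adjusted over the list alone; median log2 1.64, camera adjusted p = 1.63e-33, 0.0369 estimated). Macrophage genes were higher in 17 of 23 (19 over the list alone; 2.24, camera adjusted p = 1.79e-24, adjusted p = 0.0553 with an estimated correlation). Cell cycle genes were higher in 17 of 31 (1.12, camera adjusted p = 8.54e-15, adjusted p = 0.122 with an estimated correlation). Cytokines were higher in 13 of 28 (0.97, camera adjusted p = 1.84e-11, adjusted p = 0.0553 with an estimated correlation). Tubular injury genes were higher in 8 of 17 and lower in 1 (0.65, camera adjusted p = 8.31e-09, adjusted p = 0.0553 with an estimated correlation). The collecting duct was lower in 5 of 18 genes, 8 when adjusted over the list alone (-0.40, camera adjusted p = 0.00125, adjusted p = 0.321 with an estimated correlation), and the loop of Henle and distal tubule in 5 of 18 (-0.31, camera adjusted p = 0.0174, adjusted p = 0.472 with an estimated correlation). Per animal, both list means lay below sham without overlap (-0.545 and -0.274, exact permutation p = 0.0286 each, two-sided). Proximal tubule transport (4 higher, 3 lower, 22 not passed; camera adjusted p = 0.498) and oxidative phosphorylation (1 higher, 3 lower, 27 not passed; camera adjusted p = 0.12) did not pass. Of 20 pancreatic enzyme genes 3 were higher, 15 when adjusted over the list alone.

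B6 kidneys at day 28 showed much the same genes. Gpnmb stood 98.5-fold above sham (log2 6.62, SE 0.55), Mmp12 81.8-fold (6.35, SE 0.58), Ccl8 by 5.91 (SE 0.68), Cd68 by 4.55 (SE 0.49) and Lcn2 by 4.13 (SE 0.44), with the matrix genes Cilp (5.52, SE 0.65) and Ltbp2 (4.70, SE 0.43) and the macrophage product Retnla (5.06, SE 0.94). Hdc fell by 3.35 (SE 0.64), the kidney nuclease Dnase1 by 2.65 (SE 0.30, adjusted p = 4.63e-08), and Cpne4 fell at least 5.18-fold, while the muscle myosin Myh1 was lower by 3.49 (SE 1.15, adjusted p = 0.0278). Of 2501 genes, 1297 were higher and 1204 lower, and the count was 1537 without B6 Nx day 28 mouse 3 and 839 with only the arrays of the comparison. Matrix and fibrosis genes were higher in 26 of 28 (median log2 1.81, camera adjusted p = 4.82e-31, 0.0267 estimated), tubular injury genes in 13 of 17 (0.98, camera adjusted p = 2.06e-11, 0.0267 estimated) and macrophage genes in 19 of 23 (2.31, camera adjusted p = 2.02e-25, 0.0492 estimated). Mouse 3 stood apart in its matrix mean (10.45, others 8.90 to 9.05) and macrophage mean (9.88, others 7.92 to 8.15). The lowest Nx mice still lay 1.561 and 1.615 above the sham mean in these lists. Cell cycle genes were higher in 22 of 31 (25 over the list alone; 1.34, camera adjusted p = 1.02e-17, adjusted p = 0.0682 with an estimated correlation). Antigen presentation genes were higher in 10 of 17 (0.63, camera adjusted p = 4.12e-08, adjusted p = 0.212 with an estimated correlation). The collecting duct was lower in 11 of 18 genes (-0.62, camera adjusted p = 1.09e-08, adjusted p = 0.0625 with an estimated correlation), with the ammonia transporter Rhcg down by 1.37 (SE 0.19, adjusted p = 1.84e-06). Adipose genes were higher in 5 of 6 (2.05, camera adjusted p = 0.00892, adjusted p = 0.212 with an estimated correlation). Of the pancreatic enzyme genes, 18 of 20 were higher when adjusted over the list alone, 0 over all genes.

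Do the strains differ at day 28? Only 17 genes passed the interaction, 8 with a higher effect in FVB and 9 with a lower one, and the count was 11 without FVB Nx day 28 mouse 7. It was 3 with only the arrays of the comparison, 30 with array weights and 1003 without the arrays with pancreas transcripts, which leaves 1 Nx array per strain. The nucleic acid sensor Ifi202b (2.73, SE 0.55, adjusted p = 0.0172), the replication gene Mcm6 (2.56, SE 0.42) and the collagen Col5a2 (2.46, SE 0.52) had the higher effects. Serpina6 (-4.47, SE 0.52, adjusted p = 1.76e-06), Serpina1b (-4.04, SE 0.76) and Il5ra (-2.41, SE 0.31) had the lower ones. Mcm6, Col5a2, Serpina6 and Serpina1b differed between the strains already in sham kidneys, so their effects start from unequal levels. Effects correlated at 0.858 across genes, which are not independent replicates (Spearman 0.736), with 741 genes higher in both strains against 95.3 expected, 613 lower in both against 106 and 2 opposite. The collecting duct (0 of 18 genes passed; median log2 0.22, camera adjusted p = 0.000125, adjusted p = 0.713 with an estimated correlation) and cholesterol synthesis (0 of 16; -0.27, camera adjusted p = 0.000745, adjusted p = 0.713 with an estimated correlation) passed as lists only at the preset correlation. Tubular injury did not (0 of 17 genes passed; camera adjusted p = 0.174).

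What marks the FVB remnant at day 53, the latest time studied? Lcn2 rose 306-fold (log2 8.26, SE 0.44, adjusted p = 5.87e-18), Ccl8 204-fold (7.67, SE 0.68), Mmp12 134-fold (7.07, SE 0.58), Timp1 at least 121-fold, the injured tubule receptor Havcr1 89.1-fold (6.48, SE 0.56, adjusted p = 1.5e-12) and the monocyte chemokine Ccl12 by 6.48 (SE 0.56). The macrophage gene Ms4a6d rose by 6.56, and the pancreatic trypsinogen Prss2 was higher by 6.54 with a wide error (SE 2.80, adjusted p = 0.0468). Among the 8 largest falls, Cyp2d12 fell 93.5-fold (-6.55, SE 0.49, adjusted p = 4.4e-14) and the organic anion transporter Slc22a7 62.9-fold (-5.98, SE 0.48, adjusted p = 2.74e-13). Hpd (-5.83, SE 0.52), the distal tubule calcium binder Pvalb (-5.49, SE 0.51), the betaine-using enzyme Bhmt (-5.27, SE 0.55) and Aqp4 (-5.14, SE 0.65) fell, and so did Hdc and C8a. Of 7075 genes, 3412 were higher and 3663 lower. That split depends on scaling: with every array shifted to 1 median it was 2834 higher and 4715 lower.

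Injury, immune and matrix genes rose together in FVB kidneys at day 53. Of 17 tubular injury genes 16 were higher and 1 lower (median log2 3.16, camera adjusted p = 2.67e-13, 0.0219 estimated), with Krt20 up by 5.25 (SE 0.21, adjusted p = 2.51e-21) and the adhesion molecule Vcam1 by 4.58 (SE 0.22). Cytokines and chemokines were higher in 26 of 28 genes (2.86, camera adjusted p = 2.04e-13, 0.0388 estimated): Il34, which sustains macrophages, rose at least 7.36-fold (adjusted p = 9.36e-23) and Ccl5 by 5.83 (SE 0.48). Macrophage genes were higher in all 23 (3.87, camera adjusted p = 3.66e-16, adjusted p = 0.0867 with an estimated correlation). Matrix and fibrosis genes were higher in 27 of 28 (3.06, camera adjusted p = 1.89e-18, adjusted p = 0.0667 with an estimated correlation), and the collagen chain Col1a2 rose by 3.85 (SE 0.25). Cell cycle genes were higher in 25 of 31 (2.12, camera adjusted p = 3.42e-11, adjusted p = 0.127 with an estimated correlation). The proliferation marker Mki67 rose by 5.10 (SE 0.43). At the same time 10 of 12 genes of p53 and cell cycle arrest were higher (0.75, camera adjusted p = 0.000142, adjusted p = 0.0667 with an estimated correlation), led by Cdkn1a (3.02, SE 0.21, adjusted p = 1.23e-14). Immediate early genes were higher in 12 of 17 (1.67, camera adjusted p = 8.65e-07, adjusted p = 0.125 with an estimated correlation), among them Klf6 (2.73, SE 0.15) and Myc (3.85, SE 0.30). EGF receptor and ligand genes did not pass as a list (5 higher, 3 lower, 3 not passed; camera adjusted p = 0.734): Hbegf rose (1.95, SE 0.17), while the list mean per animal was -0.181 from sham (exact permutation p = 0.171, two-sided).

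Transcripts of immune proteins were higher too in FVB kidneys at day 53. Complement and acute phase genes were higher in 13 of 17 (14 over the list alone; median log2 3.44, camera adjusted p = 3.67e-07, adjusted p = 0.1 with an estimated correlation), with the iron oxidase Cp up by 3.44 (SE 0.17) and the fibrinogen chain Fgg by 5.69 (SE 0.43). Antigen presentation was higher in all 17 genes (1.98, camera adjusted p = 1.44e-08, adjusted p = 0.23 with an estimated correlation). Lymphocyte genes were higher in 7 of 10 (1.03, camera adjusted p = 0.0128, adjusted p = 0.295 with an estimated correlation), with Jchain of antibody-secreting cells up by 5.78 (SE 0.65). Interferon genes were higher in 12 of 19 and lower in 1 (0.76, camera adjusted p = 0.00879, adjusted p = 0.492 with an estimated correlation). Neutrophil genes did not pass as a list (2 of 6 higher; camera adjusted p = 0.381), and neither did the hypoxia response (5 of 17 higher, 4 lower; camera adjusted p = 0.788). Nrf2 targets did not pass against the other genes (6 of 16 higher, 1 lower; camera adjusted p = 0.205), but their mean per animal lay 0.434 above sham, against 0.491 in B6 at day 53 (exact permutation p = 0.0286 each, two-sided).

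Every tubule segment lost transcripts in FVB kidneys at day 53. The loop of Henle and distal tubule was lower in 16 of 18 genes (median log2 -1.79, camera adjusted p = 7.25e-12, 0.0378 estimated): the growth factor precursor Egf fell by 3.41 (SE 0.17, adjusted p = 6.19e-19), the sodium chloride cotransporter Slc12a3 by 3.02 (SE 0.20) and the potassium channel Kcnj1 by 1.81 (SE 0.11). All 31 oxidative phosphorylation genes were lower (-0.51, camera adjusted p = 8.29e-16, adjusted p = 0.0667 with an estimated correlation). The collecting duct was lower in 16 of 18 genes (-1.30, camera adjusted p = 3.08e-08, adjusted p = 0.0667 with an estimated correlation), with the anion exchanger Slc26a4 (-3.07, SE 0.21) and Rhcg (-2.67, SE 0.19) among them. Proximal tubule transport was lower in 22 of 29 genes and higher in 3 (-1.06, camera adjusted p = 8.65e-07, adjusted p = 0.241 with an estimated correlation), with the glucose transporter Slc5a2 down by 2.16 (SE 0.18) and the uptake receptor Lrp2 lower too. Fatty acid oxidation was lower in 16 of 23 genes and higher in 1 (-0.38, camera adjusted p = 0.000186, adjusted p = 0.26 with an estimated correlation). Podocyte genes did not pass against the other genes (3 higher, 9 lower, 5 not passed; camera adjusted p = 0.12), but their mean per animal differed from sham by -0.435 (exact permutation p = 0.0286, two-sided). The adrenal gene Star was higher by 4.10 (SE 0.99, adjusted p = 0.000565) beside 2 of 4 adrenal and 4 of 7 muscle genes. Per animal, these list means ranged widely over the Nx arrays, from -0.077 to 4.362 and from -1.594 to 3.674 relative to sham (exact permutation p = 0.114 and 0.886, two-sided). Of 20 pancreatic enzyme genes 1 was higher, but their mean per animal lay 3.684 above sham without overlap (exact permutation p = 0.0286, two-sided). On 2 of the 4 Nx arrays that mean passed 5 on the log2 scale.

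How far had the B6 remnant gone at day 53? Macrophage and matrix genes remained raised: Ccl8 59.1-fold (log2 5.89, SE 0.68), Gpnmb by 5.11 (SE 0.55), Mmp12 by 4.60 (SE 0.58), Cilp by 5.23, Ltbp2 by 4.69, F13a1 by 4.91 and Lcn2 by 4.44 (SE 0.44, adjusted p = 3.51e-09). The largest rise was the fat hormone Adipoq (7.48, SE 1.21, 179-fold, adjusted p = 2.36e-05), beside 4 of 6 adipose genes higher and 1 lower (median log2 2.70, camera adjusted p = 0.000808, adjusted p = 0.121 with an estimated correlation). Aqp4 fell by 3.67 (SE 0.65, adjusted p = 8.48e-05), Hdc by 3.34, the growth factor Igf2 by 3.13 (SE 0.78) and the protease Corin by 2.81 (SE 0.37), and muscle Myh1 was lower by 3.78 (SE 1.15, adjusted p = 0.0204). Egf did not pass (-0.46, SE 0.17, adjusted p = 0.0572). Of 1938 genes, 1058 were higher and 880 lower, and the count was 3288 with array weights and 1193 with other-tissue means as covariates.

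Several lists stayed raised in B6 kidneys at day 53. Tubular injury was higher in 9 of 17 genes (12 when adjusted over the list alone; median log2 0.84, camera adjusted p = 7.86e-11, 0.0248 estimated), matrix and fibrosis in 22 of 28 (25 over the list alone; 1.57, camera adjusted p = 1.41e-25, 0.0314 estimated), macrophages in 19 of 23 (2.07, camera adjusted p = 5.24e-22, 0.0427 estimated) and cytokines in 15 of 28 (0.94, camera adjusted p = 1.07e-11, 0.0393 estimated). Nrf2 targets were higher in 9 of 16 (0.39, camera adjusted p = 1.1e-06, 0.0248 estimated), with the detoxifying Ephx1 up by 1.05 (SE 0.14). Cell cycle genes were higher in 13 of 31 (0.71, camera adjusted p = 3.04e-09, adjusted p = 0.156 with an estimated correlation). The collecting duct was lower in 12 of 18 genes (-0.61, camera adjusted p = 2.41e-11, 0.0248 estimated), Slc26a4 by 1.38 (SE 0.21), and the loop and distal tubule in 6 of 18 (-0.34, camera adjusted p = 0.000783, adjusted p = 0.208 with an estimated correlation). Oxidative phosphorylation (1 of 31 genes lower; -0.04, camera adjusted p = 0.122) and proximal tubule transport (5 higher, 7 lower, 17 not passed; camera adjusted p = 0.587) did not pass, and the sulfate transporter Slc13a1 rose by 1.20 (SE 0.13) and the anion transporter Slc22a6 by 0.89 (SE 0.14).

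**Figure D3:**
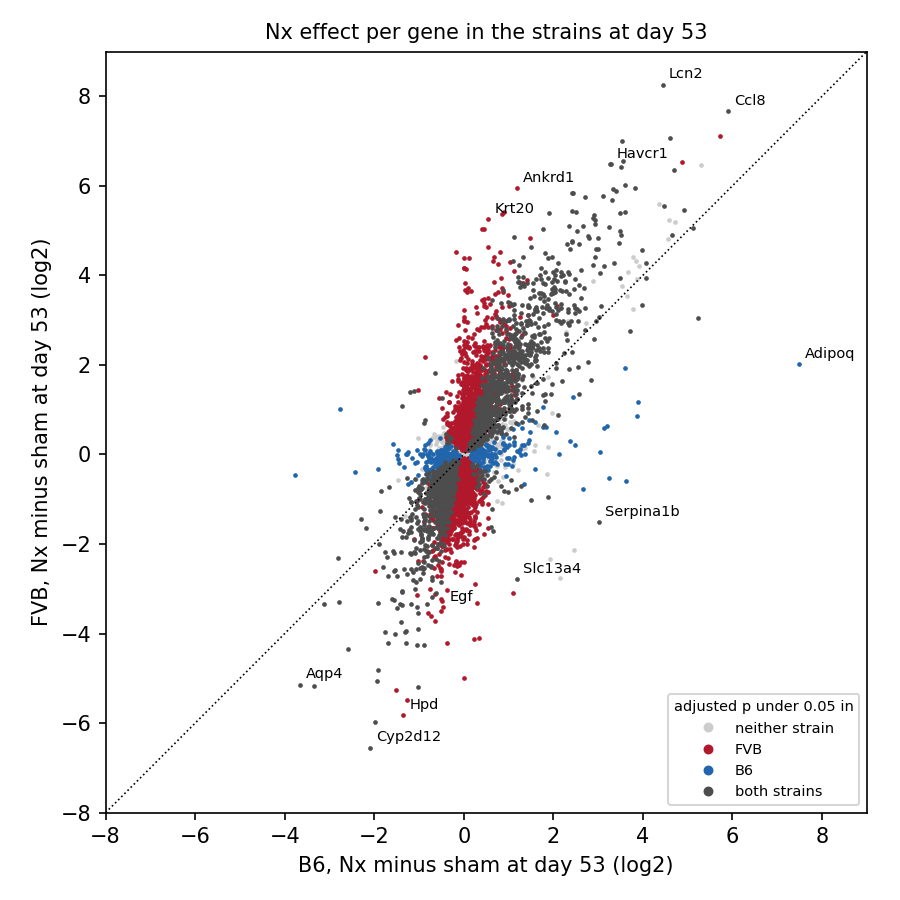
Nx against sham change at day 53 for each gene in B6 (x axis, log2) and FVB (y axis, log2), 4 animals per group, coloured by the strain in which the gene passed. The dotted line marks equal change, and the correlation over genes is 0.741.

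Where do the strains part at day 53? The interaction passed for 3839 genes, 1874 with a higher effect in FVB and 1965 with a lower one, or 1500 and 2430 with every array shifted to 1 median. With other-tissue means as covariates the count was 2492. Among the genes with a higher effect were Krt20 (4.70, SE 0.30, adjusted p = 2.2e-14), the stretch-responsive Ankrd1 (4.76, SE 0.61, adjusted p = 2.34e-07), Mcm6 (4.69, SE 0.42), the complement regulator Cfi (4.63, SE 0.56), Smpdl3b (4.60, SE 0.41), Il34 (2.89, SE 0.15, adjusted p = 5.17e-17) and Cdkn1a (2.01, SE 0.30). Egf (-2.94, SE 0.24, adjusted p = 1.79e-11), Slc12a3 (-2.65, SE 0.28), the calcium buffer Calb1 (-2.14, SE 0.19), Hpd (-4.47, SE 0.74), Serpina6 (-4.99, SE 0.52) and Slc22a8 (-2.37, SE 0.28) had lower ones. The fat gene Adipoq was also lower (-5.48, SE 1.71, adjusted p = 0.0133). Mcm6 and Serpina6 differed between the strains already in sham kidneys. Across genes, which are not independent replicates, effects correlated at 0.741 (Spearman 0.636), 868 genes were higher in both strains against 274 expected and 666 lower in both against 245. Of the genes called in both strains, 86.1% had the larger change in FVB at day 53 (slope of FVB on B6 effects 1.56), against 70.8% at day 2 (1.14) and 43.7% at day 28 (0.908).

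The day 53 difference fell into clear programs. Tubular injury had a higher effect in FVB in 14 of 17 genes (median log2 1.93, camera adjusted p = 1.88e-12, 0.0143 estimated), while the loop of Henle and distal tubule had a lower one in 15 of 18 (-1.38, camera adjusted p = 5.15e-14, 0.0143 estimated) and oxidative phosphorylation in 29 of 31 (-0.46, camera adjusted p = 3.37e-21, 0.0496 estimated), with the respiratory chain subunit Ndufs1 at -0.88 (SE 0.10). Matrix genes had a higher effect in 20 of 28 (1.32, camera adjusted p = 2.6e-10, adjusted p = 0.234 with an estimated correlation). Macrophage genes had a higher effect in 19 of 23 (1.81, camera adjusted p = 1.04e-09, adjusted p = 0.234 with an estimated correlation). Cytokines had one in 16 of 28 (1.76, camera adjusted p = 3.92e-09, adjusted p = 0.135 with an estimated correlation). Cell cycle genes had a higher effect in 21 of 31 (1.33, camera adjusted p = 1.07e-07, adjusted p = 0.24 with an estimated correlation). Immediate early genes had one in 11 of 17 (1.63, camera adjusted p = 1.14e-07, adjusted p = 0.168 with an estimated correlation). Proximal tubule transport had a lower effect in 20 of 29 genes and a higher one in 1 (-0.75, camera adjusted p = 7.39e-10, adjusted p = 0.212 with an estimated correlation). The interferon list that separated the strains at day 2 did not pass (3 higher, 1 lower, 15 not passed; camera adjusted p = 0.268). Per animal, the tubular injury score was above sham by 3.39 in FVB and 1.30 in B6 at day 53, by 2.63 and 2.45 at day 2, and by 1.09 and 1.39 at day 28 (exact permutation p = 0.0286 each, two-sided).

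How does the FVB response move between days? From day 2 to day 28 the Nx effect changed for 3324 genes, 1680 upward and 1644 downward (2324 and 1290 with every array shifted to 1 median). Slfn4 (-6.40, SE 0.44), Irf7 (-2.85, SE 0.21, adjusted p = 1.53e-12), the matrix proteoglycan Vcan (-5.90, SE 1.09), Krt20 (-3.43, SE 0.30) and Lcn2 (-3.88, SE 0.62) dropped. Cyp27b1, which activates vitamin D, came up by 4.00 (SE 0.85), Fam151a by 3.83 (SE 0.39) and Cyp2d12 by 3.64 (SE 0.69). Proximal tubule transport came up in 24 of 29 genes (median log2 1.12, camera adjusted p = 3.54e-17, adjusted p = 0.0973 with an estimated correlation). Oxidative phosphorylation came up in 27 of 31 (0.33, camera adjusted p = 3e-14, adjusted p = 0.155 with an estimated correlation). Interferon genes dropped in 13 of 19 (-1.51, camera adjusted p = 6.7e-12, adjusted p = 0.12 with an estimated correlation). Tubular injury genes dropped in 11 of 17 (-1.37, camera adjusted p = 1.1e-08, adjusted p = 0.0973 with an estimated correlation).

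From day 28 to day 53 the FVB effect grew again, for 3462 genes, 1799 upward and 1663 downward (1311 and 2251 with every array shifted to 1 median). Krt20 rose by 5.03 (SE 0.30, adjusted p = 2.24e-15), Saa1 by 4.81 (SE 0.84), Lcn2 by 4.30 (SE 0.62, adjusted p = 2.31e-06) and Il34 by 2.81 (SE 0.15). Pvalb (-5.04, SE 0.72), Cyp2d12 (-4.89, SE 0.69), Slc22a7 (-4.47, SE 0.68), Bhmt (-3.93, SE 0.78) and Egf (-3.10, SE 0.24, adjusted p = 3.49e-12) dropped. Tubular injury rose in 16 of 17 genes (median log2 2.40, camera adjusted p = 2.44e-14, 0.00651 estimated), the loop and distal tubule dropped in 15 of 18 (-1.48, camera adjusted p = 9.09e-17, 0.00651 estimated) and oxidative phosphorylation in 29 of 31 (-0.43, camera adjusted p = 5.83e-23, 0.0358 estimated). Cytokines rose in 18 of 28 genes (1.85, camera adjusted p = 6.76e-10, adjusted p = 0.0782 with an estimated correlation). The collecting duct dropped in 11 of 18 (-0.88, camera adjusted p = 1.47e-08, adjusted p = 0.0683 with an estimated correlation). Proximal tubule transport dropped in 18 of 29 and rose in 1 (-0.66, camera adjusted p = 4.36e-10, adjusted p = 0.13 with an estimated correlation).

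How does the B6 response move between days? From day 2 to day 28 the Nx effect changed for 1167 genes, 638 upward and 529 downward, or 2521 genes with array weights. Cxcl5 (-5.33, SE 0.42, adjusted p = 8.85e-12), Krt20 (-4.29, SE 0.30, adjusted p = 2.98e-13), Mmp7 (-4.34, SE 0.53), Aurka (-3.49, SE 0.30) and the neutrophil gene S100a9 (-4.72, SE 1.40) dropped. Cyp27b1 came up by 5.10 (SE 0.85, adjusted p = 6.49e-05) and Slc7a7 by 2.70 (SE 0.34). The fat genes Ucp1 (7.67, SE 2.10), Adipoq (5.77, SE 1.71), Cox8b (5.73, SE 1.63) and Thrsp (5.59, SE 1.73) also came up. Cell cycle genes dropped in 19 of 31, 26 when adjusted over the list alone (median log2 -1.46, camera adjusted p = 4.32e-26, adjusted p = 0.0669 with an estimated correlation). Tubular injury genes dropped in 8 of 17 (-0.63, camera adjusted p = 4.36e-08, adjusted p = 0.0771 with an estimated correlation). Proximal tubule transport came up in 17 of 29 (0.63, camera adjusted p = 1.08e-16, adjusted p = 0.0771 with an estimated correlation). Macrophage genes did not pass (1 of 23 lower; camera adjusted p = 0.172). From day 28 to day 53 limma called 0 genes in B6, with 405 below an unadjusted p of 0.05 against 659 expected, though without the arrays with pancreas transcripts, which leaves 1 Nx array at day 28, the count was 987. As lists, cell cycle (0 of 31 genes passed; -0.52, camera adjusted p = 3.49e-08, adjusted p = 0.921 with an estimated correlation) and matrix (0 of 28; -0.31, camera adjusted p = 0.000277, adjusted p = 0.921 with an estimated correlation) passed only at the preset correlation.

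Do the strains differ before any nephrectomy? Over sham kidneys of all days, 12 animals per strain, 4278 genes differed, 2223 higher in FVB and 2055 lower. Snap91 (log2 5.57, SE 0.16), Abhd1 (5.50, SE 0.14), Serpina1b (5.41, SE 0.31), Greb1 (4.93, SE 0.12) and Serpina6 (4.83, SE 0.21) were highest in FVB. The lysosomal enzyme Galc (-7.80, SE 0.10, adjusted p = 1.68e-40), the thyroxine carrier Ttr (-7.54, SE 0.56), Mndal (-6.61, SE 0.15), the class II antigen H2-Eb1 (-6.09, SE 0.26) and Zfp874a (-5.43, SE 0.08) were lowest, and Mcm6 (-3.64, SE 0.17) and Col5a2 (-3.24, SE 0.21) were lower as well. A base that differs between strains under a probe changes hybridisation on its own, and such probes were not removed here. Serpina6, Serpina1b, Mcm6 and Col5a2 were also named above for strain differences of the Nx effect. Whether their unequal sham levels or their probes shape those differences was not tested. The unfolded protein and amino acid response was higher in FVB in 12 of 19 genes, 14 when adjusted over the list alone (median log2 0.35, camera adjusted p = 0.000265, adjusted p = 0.679 with an estimated correlation), with Creld2 at 1.25 (SE 0.12).

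**Figure D4:**
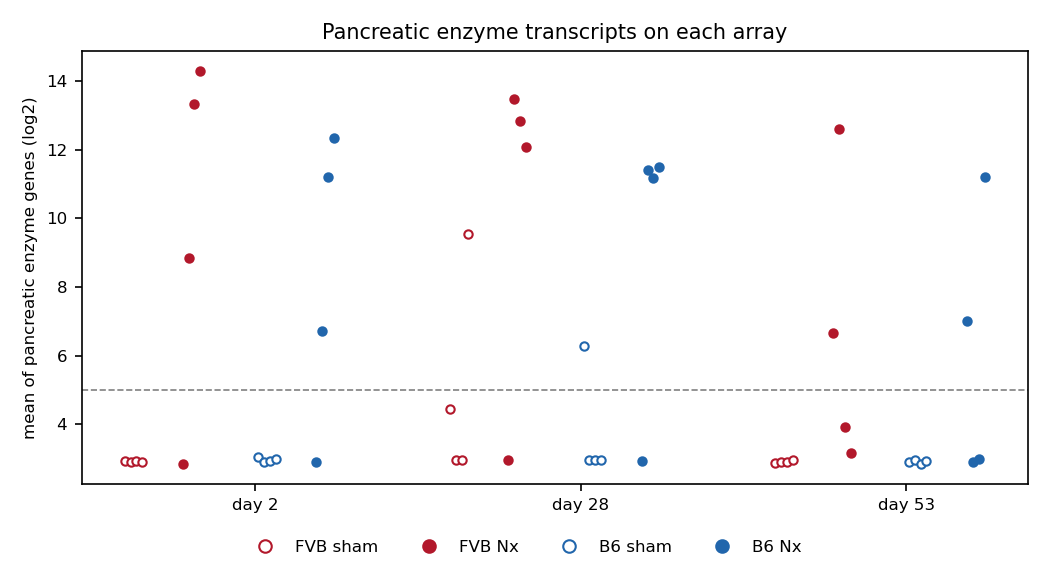
Mean of the pancreatic enzyme genes (log2, y axis) for each of the 48 arrays, by strain, surgery and day (x axis). The dashed line lies at 5, above which 16 of 24 Nx and 2 of 24 sham arrays lie.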

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

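The splits of the surgery and sham comparisons were planned before the values were seen, while the splits of strain differences and of changes between days, and all tests of explanations below, were chosen after those results were seen.

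Could arbitrary splits of the arrays call this many genes? For each surgery comparison the same 8 arrays can be split in 35 ways, and in each only 1 of 35 splits, the real one, called as many genes (exact p = 0.0286, the smallest possible). For FVB the real split called 7221 genes at day 2 against at most 4306 in another split, 2129 against 237 at day 28 and 7075 against 3007 at day 53. For B6 it called 5874 against 2568, 2501 against 800 and 1938 against 56, so chance is excluded at the level that 4 against 4 arrays allow. For sham FVB against B6, 1 of 100 splits reached the real 4278 genes and the highest other called 671.

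For strain differences and changes between days, other splits carry the surgery effect with them. With that effect left in, 18, 8 and 6 of 100 splits called as many genes as the real strain difference at days 2, 28 and 53 (highest other 6166, 314 and 5591). For the changes between days, 4 and 3 of 100 did so in FVB (highest other 6279 and 6261) and 6 and 100 in B6 (3995 and 2749). After these counts were seen, the splits were repeated with the means of surgery and of strain or day removed. Then 1 of 100 splits reached the real 581 genes at day 2 (highest other 131) and 1 of 100 the 3839 genes at day 53 (highest other 2346). For the day 28 strain difference, 2 of 100 splits reached the real 17 genes and the highest other called 139, several times the real count. Why that split called so many was not traced. In FVB, 1 of 100 splits reached the real 3324 genes from day 2 to day 28 (highest other 1045) and 1 of 100 the 3462 from day 28 to day 53 (highest other 2478). In B6, 1 of 100 reached the 1167 genes from day 2 to day 28 (highest other 285), and from day 28 to day 53 the real count is 0, which all 100 of 100 splits reach by construction (highest other 26), so the splits say nothing there.

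Single animals stood apart in 18 of 192 tests of 1 animal against the other 3 of its group, where 9.6 are expected by chance. B6 Nx day 28 mouse 3 stood apart in its matrix mean (10.45 against 8.90 to 9.05), macrophage mean (9.88 against 7.92 to 8.15) and pancreas mean (2.94 against 11.18 to 11.49). Pancreas means also stood apart for FVB Nx day 28 mouse 2 (2.94 against 12.08 to 13.49) and B6 sham day 28 mouse 1 (6.29 against 2.95 to 2.97). The latter differed in interferon (7.04 against 6.87 to 6.89) and muscle genes (4.00 against 4.06 to 4.07). FVB Nx day 28 mouse 3 had a muscle mean of 6.23 against 3.50 to 3.75 and a Gapdh 3 prime minus 5 prime difference of 0.332 against 0.269 to 0.270. The adrenal mean was high in B6 sham day 2 mouse 4 (6.91 against 3.73 to 3.87). Adrenal means were also flagged in B6 sham day 28 mouse 5 (3.92 against 3.83 to 3.84) and FVB sham day 28 mouse 1 (3.91 against 3.78 to 3.79). Those 2 shifts are small and stood apart because the other 3 animals lay close together, since the test weighs spacing and not size. The fat mean was 9.71 in FVB Nx day 2 mouse 4 (others 5.31 to 5.67), and the macrophage mean 7.18 in B6 sham day 2 mouse 5 (others 6.88 to 6.92). Along the axis of surgery, B6 sham day 53 mouse 1 (34.86 against 43.66 to 45.43), FVB sham day 28 mouse 4 (27.88 against 42.80 to 45.38) and FVB Nx day 53 mouse 10 (-44.41 against -61.03 to -60.13) lay closer to the middle. The Actb 3 prime minus 5 prime difference was 2.523 in B6 Nx day 53 mouse 7 (others 2.123 to 2.186).

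Among the lists, those that separated the strains also with an estimated correlation were interferon at day 2 (median 1.73) and, at day 53, tubular injury (1.931), oxidative phosphorylation (-0.457) and the loop of Henle and distal tubule (-1.382).

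Pancreatic enzyme transcripts passed a log2 mean of 5 on 16 Nx arrays. If pancreas tissue entered the RNA, all enzymes should rise on the same arrays. Over the 24 Nx arrays their median pairwise correlation was 0.973 (lowest 0.651), as pancreas tissue in the RNA would give. Enzyme genes switched on together would give it too. A list of pancreatic islet genes reached 4.797 above the sham mean on the highest FVB Nx array at day 2 and 2.907 at day 28. The highest sham arrays reached 0.271 and 0.394. Its group means did not separate Nx from sham there (exact permutation p = 0.686 and 0.257, two-sided), and at day 53 the FVB difference was -0.114. Whether islet genes rose on the arrays with enzymes was not tested, so they do not settle the source. If injured tubules switched these genes on, the enzyme mean should follow the tubular injury mean within groups. The correlation was -0.282 (95% interval -0.651 to 0.115, permutation p = 0.245, Spearman -0.285, and -0.403 without the 2 farthest arrays), which argues against the enzyme mean following injury closely within groups. It cannot exclude that injury switched these genes on, because the injury mean varied little within some groups (SD 0.108 in FVB Nx at day 2). Where in handling such tissue could enter is not recorded in the labels.

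The larger FVB effect at day 53 has several possible causes other than the kidney's own response. The median strain difference over the 3839 genes was 0.708, and with pancreas, fat, adrenal and muscle means as covariates it was 0.705 (99.5%), so RNA of other tissues on the arrays does not account for its median size, though the number of genes called fell from 3839 to 2492. With the 3 prime to 5 prime differences as covariates, as a measure of RNA degradation, it was 0.673 (95%). A lower share of tubule cells with no change in the other cells would raise the markers of all other cells. Yet the FVB effect was lower than the B6 effect for endothelium (-0.316) and podocytes (-0.208) and higher for macrophages (1.961; exact permutation p = 0.0286 each, two-sided). For fibroblasts the difference of 0.264 did not pass (exact permutation p = 0.257), which does not show that they were alike. These permutations exchanged only the Nx arrays, each taken relative to the sham mean of its strain. The p-values therefore leave out the spread of the sham arrays. None of these tests separates an earlier from a stronger injury in FVB.

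The interferon response of FVB kidneys at day 2 may in part reflect an exposure shared by the FVB animals of day 2. The mean of the FVB sham mice of day 2 lay 0.744 above that of the FVB sham mice of the other days (exact permutation p = 0.0263, two-sided), 25.5% of the 2.916 by which the Nx mice of day 2 did so. Only 2 of the 4 mice were raised, mouse 2 (7.54) and mouse 4 (8.08), while the others (6.36 and 6.57) lay within the 6.15 to 6.64 of the other days. Without mouse 4 the difference was 0.43 (exact permutation p = 0.0788, two-sided), so an exposure is left open and cannot be told apart from an effect of recent surgery. In FVB at day 53 the interferon mean was 0.882 above sham against 2.172 at day 2, while the macrophage mean was 3.807 above sham against 3.548. This argues against macrophage number alone, but only if interferon transcripts per macrophage were alike on both days. That was not tested, so a part played by the macrophages of day 2 is not excluded.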

How the results depend on the processing

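The settings without pancreas transcripts, with other-tissue means as covariates and with 3 prime to 5 prime differences as covariates were chosen after the results were seen, and all others before. The cause of a change was not tested unless stated.

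Scaling moved no count by more than 1.5 times. With only the arrays of the comparison in the fit, B6 at day 28 called 839 genes (2501 with all arrays), the strain difference 324 at day 2 (581) and 3 at day 28 (17). Fewer arrays leave fewer residual degrees of freedom by construction, but every surgery comparison loses them alike. The spread also comes from those arrays alone, and B6 Nx day 28 mouse 3 deviated widely from its group (SD over genes 0.5203, array weight 0.268). Which of these lowered the counts was not tested. With array weights, B6 at day 53 called 3288 genes (1938), the day 28 strain difference 30 (17) and the B6 change from day 2 to day 28 2521 (1167). With no filter, the B6 change from day 28 to day 53 called 1 gene (0).

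With the 4 other-tissue means as covariates, B6 at day 53 called 1193 genes (1938) and the day 53 strain difference 2492 (3839). The fat gene Thrsp, in the B6 change from day 2 to day 28, turned from 5.59 to -0.265 in this setting, where a mean of fat genes is itself a covariate. Without the arrays with pancreas transcripts, FVB at day 28 called 635 genes (2129), the day 28 strain difference 1003 (17) and the B6 change from day 28 to day 53 987 (0). Those groups then hold 1 Nx array at day 28, B6 Nx day 28 mouse 3 and FVB Nx day 28 mouse 2, and that array is assumed to vary like the others, so these counts may reflect 2 unusual animals (matrix mean of the former 10.45).

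Leaving out single arrays, the day 2 strain difference ranged from 343 (without FVB Nx day 2 mouse 2) to 951 (without FVB Nx day 2 mouse 5). B6 at day 28 ranged from 1537 (without B6 Nx day 28 mouse 3) to 2615 (without mouse 9), and the day 28 strain difference from 11 (without FVB Nx day 28 mouse 7) to 24 (without B6 Nx day 28 mouse 9). The B6 change from day 28 to day 53 stayed between 0 (without B6 Nx day 28 mouse 3) and 1 (without B6 sham day 28 mouse 3). FVB at day 53 stayed between 6611 and 6949 and the day 53 strain difference between 3392 and 3946.

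Of 310 list tests, which leave out the changes between days, 147 passed at the preset correlation and 19 with the estimated correlation. Mouse number as a block gave 7328 genes for FVB at day 2, 2072 for FVB at day 28, 2638 for B6 at day 28 and 24 for the day 28 strain difference. The 2 log scales planned for linear values were not applicable because the values are log2, and camera has no robust setting.

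Of 432 results for named genes, 430 kept their call under each of the 2 scalings, 391 with only the arrays of the comparison, 407 with the 4 other-tissue means, 412 with the 3 prime to 5 prime differences and 381 without the arrays with pancreas transcripts. Among those that had passed, Thrsp was the only 1 that changed sign.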

Other observations

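The comparisons across days, the genes with opposite effects, the 5 lists and the settings with other-tissue means used below were chosen after the results were seen.

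In both strains the late response shared more genes with the acute one than expected by chance. Of the genes higher in FVB Nx kidneys, 2434 were shared by day 2 (3273) and day 53 (3412) against 848 expected by chance, and of those lower 2843 were shared (3948 and 3663) against 1098. The effects correlated at 0.84 across genes, which are not independent replicates (Spearman 0.831). In B6 the overlaps were 821 against 213 expected and 663 against 215, with a correlation of 0.705. Because no FVB animal was followed over time, a relapse of the same program and a new injury with the same outcome could both give this picture, and the array splits (1 of 100 for the growth from day 28 to day 53, highest other 2478) speak only against chance.

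At day 53, 51 genes passed in opposite directions in the strains, 37 lower in FVB and higher in B6 and 14 the reverse. All 51 passed the interaction, which their selection for opposite effects made likely, so this adds no separate support. Solute carriers were 9 of the 51 though only 293 of all genes, 8 of them lower in FVB and higher in B6. The family was noticed among these same genes, so no test of it is given. The sulfate carrier Slc13a4 was at -2.78 in FVB and 1.18 in B6 (interaction -3.96, adjusted p = 3.78e-10), Slc22a8 at -1.72 and 0.65, Slc13a2 at -1.22 and 0.63, Slc26a6 at -0.77 and 1.16 and the bile acid carrier subunit Slc51a at -0.84 and 0.99. Among the reverse were Cebpd (1.09 and -1.37), Socs2 (1.42 and -1.12) and Nfil3 (1.39 and -1.21).

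Lists written after the values were seen, with the genes named above removed, ask how far the fall of tubule transcripts goes. In whole-kidney RNA these lists cannot tell a change within tubule cells from a changed mix of cells. Amino acid breakdown was lower in 23 of 24 genes and higher in 1 in FVB at day 2 (median log2 -1.20, camera adjusted p = 1.32e-09) and again at day 53 (-1.15, camera adjusted p = 3.84e-10), each adjusted p = 0.173 with an estimated correlation. In B6 it was lower in 19 of 24 at day 2 (-0.81, camera adjusted p = 1.65e-09). At day 53, 2 were higher and 4 lower in B6, and the day 53 interaction was lower in 22 of 24 (-1.05, camera adjusted p = 2.14e-14, adjusted p = 0.143 with an estimated correlation). Transcription factors of mature tubules were lower in 15 of 19 in FVB at day 53 (-0.78, camera adjusted p = 0.000341, adjusted p = 0.143 with an estimated correlation). At day 2 they were lower in 16 of 19 in FVB (camera adjusted p = 0.000227) and 15 of 19 in B6 (camera adjusted p = 0.000985). At day 28 they were lower in 6 of 19 in FVB (camera adjusted p = 0.00669) and 10 of 19 in B6 (camera adjusted p = 0.000155). In B6 at day 53 they were lower in 6 of 19 (camera adjusted p = 0.00371), and the day 53 interaction was lower in 10 (camera adjusted p = 0.00372). Targets of the stretch sensor YAP were higher in 10 of 17 and lower in 1 in FVB at day 53 (camera adjusted p = 0.0148), and in B6 higher in 7 and lower in 2 at day 2 (camera adjusted p = 0.0302). The day 53 interaction passed too (6 higher, camera adjusted p = 0.0055). The YAP list did not pass in FVB at day 2 (8 higher, 2 lower, camera adjusted p = 0.0536) or day 28 (0.142), nor in B6 at day 28 (0.606) or day 53 (0.694). Keratins were higher in 4 of 6 at day 53 in FVB (camera adjusted p = 0.0284) and in B6 (camera adjusted p = 0.00651), and their interaction did not pass (camera adjusted p = 0.166). Genes of kidney development did not pass as a list in any of 14 contrasts (FVB at day 53: 4 higher, 6 lower, 5 not passed, camera adjusted p = 0.606). None of these 70 tests passed with an estimated correlation, the smallest adjusted p being 0.143.

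Fat transcripts differ between groups in a way that kidney biology need not explain. Of 9 fat genes, 3 were lower in B6 Nx kidneys at day 2, 3 higher at day 28 and 6 higher at day 53 (median log2 -1.49, 2.42 and 3.59), and none passed in FVB. The mean of the adipose list set in advance was higher per animal in FVB Nx kidneys at day 28 too (0.865, exact permutation p = 0.0286, two-sided). With pancreas, fat, adrenal and muscle means together as covariates the B6 day 53 count fell from 1938 to 1193. That fall cannot be assigned to fat alone. In B6 at day 53 the fat mean also separated Nx (1.815 to 5.022 relative to sham) from sham arrays (-0.128 to 0.104). Such a covariate widens the error of the surgery effect by construction, so whether part of the count comes from fat in the sample is left open.

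The arrays cannot say whether the FVB animals at day 53 share 1 course, since each was measured once and 4 animals make a group. Protein, histology and kidney function of these animals were not used here. A test of the interferon finding would need FVB sham and untouched animals of the same days, because 2 of the 4 sham mice of day 2 had interferon means of 7.54 and 8.08, above the 6.15 to 6.64 of the sham mice of other days (mean difference of all 4 mice 0.744). Dissection records or a repeat with the capsule removed would settle whether the 0.973 correlation of pancreatic enzymes reflects tissue carried along.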
